A study of Mus musculus with 2 samples.

How the data were processed

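H3K4me3 was measured by chromatin immunoprecipitation followed by sequencing in mouse fetal liver, in 2 biological replicates of the same tissue and age. The analysis used 4 peak lists on the mm10 assembly, which were 1 list for each replicate, 1 pooled list from both replicates together, and 1 list that the authors call replicated. Per the deposited file records, each replicate's list was derived from the filtered alignment of that replicate. The list of replicate 1 also drew on 2 further files and the list of replicate 2 on 1 further file, whose roles are not given in the sources used here. The pooled list drew on both alignments, and the replicated list was derived from the other 3 peak lists. The aligner, the peak caller, their versions and the read filters are not given in the sources used here. A control experiment is named as possible in the labels and was not analysed here.

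In all 4 lists each peak carries a signal value, which is the authors' deposited measure of the peak's enrichment, and what it is relative to is not given. It was used to describe, rank or filter peaks within 1 list, and between lists only in the correlations across peaks shared by the replicates. Each peak also carries the −log10 of a p-value and the −log10 of a q-value as deposited, computed by the authors' peak caller. No read counts accompany the lists, so the sequencing depth is unknown, and neither a difference in depth nor counting error of a single peak can be given. Confidence intervals of shares are 95% Wilson intervals over peaks or genes and cover the counting of peaks or genes only.

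Peak positions were set against the GRCm38.p6 genome with the GENCODE M21 annotation, which have the same coordinates as mm10, and every peak on chromosomes 1 to 19, X and Y lay within the length of its chromosome. Peaks on scaffolds outside these chromosomes were left out of the comparisons. Positions are given counting from 1. A promoter was defined as the stretch within 1 kb of the transcription start site (TSS) of any annotated transcript. A protein-coding gene was called marked when a peak of the replicated list overlapped a promoter of the gene, and 21938 protein-coding genes were used. Peaks off promoters were assigned to exons, then introns, then intergenic sequence. A domain was built in each replicate by merging peaks at most 1 kb apart, and a gene's domain was the widest one overlapping a promoter of the gene. Its width was averaged over the 2 replicates and is given with the SD (n = 2). Asymmetry was measured on genes with 1 TSS and no TSS of another gene within 5 kb. CpG content was the ratio of observed to expected CpG within 500 bp of a TSS, averaged over the distinct TSSs of a gene.

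Peaks of both replicates were called shared when they overlapped by 1 bp or more, and the chance level came from 100 shuffles of the other list within chromosomes. The chance share of peaks at promoters came from 20 shuffles. Spearman's rho and Pearson's r of log2 signal values across shared peaks describe how far the values of the lists go together, without a p-value, since peaks are not independent replicates. The shares of 25 gene lists that were marked were compared with all other protein-coding genes by Fisher's exact test, two-sided. Median domain width of each list with at least 5 members marked in both replicates was placed among 10000 random lists of the same size drawn from marked genes. Membership of each list in the broadest 5% of domains was tested by Fisher's exact test, two-sided. P-values were adjusted over lists by the method of Benjamini and Hochberg, with a threshold of 0.05. For domain width the planned description was the percentile alone, and the two-sided p with its adjustment was added later. The CpG content of marked and unmarked genes was compared by a permutation test with 100000 resamples. Genes within a list are not independent replicates, so these tests describe these 2 libraries.

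Gene lists, tests, thresholds and the rule for naming genes were written before the data were examined. The rule named the 20 marked genes with the broadest mean domain and the 10 with the highest peak signal value in the replicated list. It also named the 3 broadest marked members and the first 3 unmarked members by alphabet of each list, every member of the globin and Y-linked lists, and the 5 highest peaks more than 5 kb from any TSS. Genes named outside the rule are introduced as chosen after their values were seen. Of the list members, 3 symbols were absent from the annotation (Ahsp, Hbb-b1 and Hbb-b2) and were not analysed here, and 7 non-coding genes are given as values outside the tests. Alas2, Des, Hoxa9 and Hoxb4 each stood in a pair of lists.

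The alternatives tried were promoter windows of 500 bp and 2 kb, the 5′ end of each gene as its only TSS, peaks with −log10 q of at least 2, the peak summit in place of any overlap, and the pooled list. Further ones were merge distances of 0 bp and 3 kb, the broadest 10% of domains, overlaps of at least 50%, random lists matched on deciles of promoter CpG content, and each replicate alone.

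The overlap of replicates, the share marked, domain width, the broadest domains and asymmetry were tested on simulated data, while the CpG comparison, the share of peaks at promoters and the correlations were not. For the share marked, 100% of simulated lists with a true share of 95% against 60% were called among 21938 genes, and 0% of unchanged lists. For domain width over 13457 genes, 40% of lists of 20 genes that were 1.5-fold wider, 100% of those 3-fold wider and 5% of unchanged ones were called, so most lists of that size that are 1.5-fold wider would be missed. Smaller lists were not simulated. For the broadest domains over 13457 genes, 100% of lists with 10 of 20 members among them and 0% of lists at the base rate were called. The counts of such lists are set by their definition, so these figures are not taken as a power or an error rate. Replicate overlap recovered 100% of the shared peaks in simulated lists of 8000 peaks, which also held unshared ones. A simulated asymmetry of 1000 bp came back as 1000 bp over 3245 genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, numba 0.67.0 and matplotlib 3.10.9.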

Results

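The trimethylated form of lysine 4 of histone H3 (H3K4me3), a mark of active and poised promoters, was mapped in liver from mouse embryos at embryonic day 14.5. At this stage the liver is the main site of blood formation and holds erythroid precursors beside immature hepatocytes. The series has 1 group of 2 biological replicates, each from pooled male and female embryos of the B6NTac;B6NCrl/Lap strain, and no treated group. The comparisons are therefore between the replicates, between regions of the genome and between groups of genes. Replicate 1 had 28556 peaks covering 35.2 Mb with a median width of 772 bp, and replicate 2 had 22151 peaks covering 28.7 Mb with a median width of 986 bp. The pooled list held 24540 peaks. The replicated list held 22316 peaks with a median width of 1194 bp, and 100% of them had identical positions in the pooled list. Of the replicated peaks, 85.3% overlapped a peak in both single-replicate lists.

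The first comparison asked how far the replicates showed the same marked regions. Of the peaks of replicate 2, 97.3% (95% Wilson interval 97.08 to 97.51%) overlapped a peak of replicate 1, against a mean of 2.93% for shuffled positions. In the other direction 69.5% (69.0 to 70.0%) of the peaks of replicate 1 overlapped a peak of replicate 2, against 2.29% for shuffled positions. The 8710 peaks found in replicate 1 alone were narrow and weak, with a median width of 268 bp and a median signal value of 3.45. The 19837 shared peaks of replicate 1 had a median width of 1387 bp and a median signal value of 14.9. Promoters held 32.7% of the peaks of replicate 1 alone and 75.9% of the shared ones, while introns held 39.8% and 10.96%. Replicate 2 had 597 peaks of its own. Across the 19837 shared peaks of replicate 1, signal values in the lists correlated with a Spearman's rho of 0.895 and a Pearson's r of 0.905 on the log2 scale, and widths with a rho of 0.878. These are correlations across peaks, which are not independent replicates.

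Most peaks lay at promoters. The share of peaks at a promoter was 62.7% in replicate 1 and 72.7% in replicate 2, with a mean of 67.7% ± 7.07 (SD, n = 2). Shuffled positions gave 9.46% ± 0.176 (SD, n = 2), far below either replicate. Introns held 16.8% ± 4.24, intergenic sequence 10.6% ± 1.73 and exons off promoters 4.92% ± 1.10 (SD, n = 2) of the peaks. Peaks at promoters were wider than other peaks, with medians of 1464 bp and 352 bp in replicate 1 and of 1407.5 bp and 396 bp in replicate 2. In the replicated list 70.9% of peaks lay at a promoter.

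Of the 21938 protein-coding genes, 13805 (62.9%) were marked. The share was 64.2% in replicate 1 and 61.5% in replicate 2, with a mean of 62.9% ± 1.91 (SD, n = 2). Marked promoters were rich in CpG, the dinucleotide whose clusters form CpG islands. The median ratio of observed to expected CpG was 0.558 at marked and 0.192 at unmarked genes. The difference of 0.367 had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. From the CpG-poorest to the CpG-richest decile of genes, the marked share went from 2.14% to 97.3%. The change was steepest in the middle, from 21.7% in decile 3 to 78.7% in decile 5. Around isolated start sites the mark reached further into the gene than upstream of it. The median domain extended 1072.5 bp ± 81.3 downstream and 381.5 bp ± 46.0 upstream (SD, n = 2). The median difference per gene was 668 bp ± 22.3 (SD, n = 2), and 87.8% of domains were longer downstream, over 758 genes in replicate 1 and 722 in replicate 2.

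**Figure D1:**
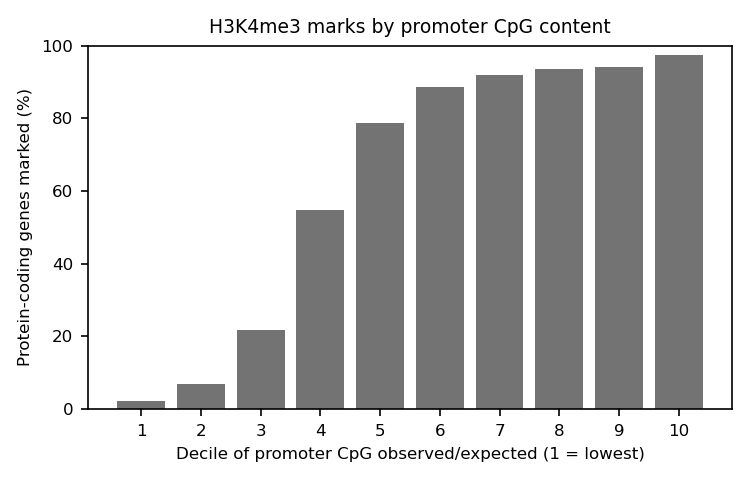
Share of protein-coding genes with an H3K4me3 peak within 1 kb of a TSS (y axis, percent) in each decile of promoter CpG observed/expected (x axis, decile 1 the lowest). The bars go from 2.14% in decile 1 to 97.3% in decile 10.

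Gene lists fixed in advance were used to ask which cell types and pathways of the fetal liver carried the mark. Of 25 lists, 9 were marked more often than other genes, 7 less often and 9 did not pass the test. The hepatocyte lists of transcription factors and secreted proteins were largely marked. The peaks come from whole liver, so they do not show which cells carry a mark. Among hepatic transcription factors 19 of 20 genes (95%) were marked, against 62.9% of other genes (adjusted p = 0.00418, Fisher's exact test). Marked members included Gata6, Prox1 and Onecut2, regulators of liver bud and hepatoblast development, and the unmarked one was Nr1i3, the nuclear receptor CAR that induces drug metabolism. Proteins secreted by fetal hepatocytes were marked in 23 of 25 cases (92%, adjusted p = 0.00382, Fisher's exact test). They included Rbp4, the plasma carrier of retinol, Trf, the iron carrier transferrin, and Ttr, the thyroxine carrier transthyretin, whose highest peak lay beside its TSS without covering it. The unmarked members were Apoc3 and Fetub. Cholesterol synthesis genes were marked in 20 of 20 cases (adjusted p = 0.000341, Fisher's exact test), among them Hmgcr, the rate-limiting enzyme, Hmgcs1 and Dhcr24.

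Genes of the postnatal hepatocyte were marked less often, at 10 of 26 (38.5%, adjusted p = 0.0212, Fisher's exact test). Unmarked members included Abcb11, the bile salt export pump, Cps1, the entry enzyme of the urea cycle, and Cyp1a2, a drug-metabolizing cytochrome P450. Marked members included Glul, which makes glutamine, and Fah and Pah, enzymes of tyrosine and phenylalanine breakdown, and the peak at Glul also covered the TSS of Teddm2. Coagulation and complement genes did not pass the test against other genes, with 17 of 25 marked (68%, adjusted p = 0.776, Fisher's exact test). Serpinc1 (antithrombin) and F2 (prothrombin) were marked, and C4bp, C5ar1 and C6 were not. The peak at C8g also covered the TSS of Fbxw5. In a permutation test against random lists matched on CpG content, 34.1% of postnatal genes would be marked, so that the difference turned direction and did not pass (adjusted p = 0.764), and that of cholesterol synthesis did not pass either (89.0% expected, adjusted p = 0.233). For coagulation and complement 19.3% would be marked, and the list then passed this permutation test as higher (adjusted p = 6.25e-05). Counting a peak by its summit, 80% of hepatic transcription factors were marked (adjusted p = 0.161, Fisher's exact test).

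The erythroid program was marked almost completely. Of the erythroid list 28 of 29 genes (96.6%) were marked (adjusted p = 0.00018, Fisher's exact test), among them Ank1, which anchors the red cell membrane skeleton, Nfe2, a subunit of the transcription factor NF-E2, and Dmtn, the actin-bundling protein dematin. The exception was Slc25a37 (mitoferrin-1, which carries iron into mitochondria), on chromosome 14 at 69241848 to 69285112, where 100% of the 31-base words around the gene's 5′ end occur more than once in the genome. The enzymes and transporters of heme synthesis were marked in 11 of 11 cases (adjusted p = 0.0167, Fisher's exact test), including Hmbs, Fech and Cpox. With the summit rule 90.9% of them were marked (adjusted p = 0.0950, Fisher's exact test). Genes of haematopoietic stem and progenitor cells were marked in 18 of 18 cases (adjusted p = 0.000878, Fisher's exact test), with Lyl1, Runx1 and Meis1, transcription factors of early blood cells, as the broadest. With the 5′ end of the gene as the only TSS, 77.8% of that list was marked (adjusted p = 0.207, Fisher's exact test).

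Other blood lineages were marked less often or did not pass the test. The myeloid and macrophage list had 8 of 25 genes marked (32%, adjusted p = 0.00578, Fisher's exact test). Prtn3, a neutrophil protease, Csf1r, the receptor for the macrophage growth factor, and Fcer1g were marked, although the highest peak at Prtn3 also covered the TSS of Plppr3 and that at Csf1r lay within 1 kb of a TSS of the gene without covering any, while Adgre1 (F4/80) and the complement genes C1qa and C1qb were not. The lymphoid list had 7 of 21 genes marked (33.3%, adjusted p = 0.0124, Fisher's exact test). Gata3, Lck and Vpreb1 were marked, the last by a peak that also covered the TSS of Top3b, while Blk, Cd19 and Cd3d were not. For megakaryocytes 10 of 18 genes were marked (55.6%, adjusted p = 0.769, Fisher's exact test), including Nbeal2, Fli1 and Gp9, the last by a peak beside its TSS, but not Clec1b, Gp6 or Mpl, the thrombopoietin receptor. In the CpG-matched permutation test the lymphoid difference did not pass (44.5% expected, adjusted p = 0.318) and the myeloid one turned direction (19.6% expected, adjusted p = 0.226). In the list of replicate 1 alone, 44% of the myeloid list was marked and did not pass Fisher's exact test (adjusted p = 0.0900), against 24% in replicate 2 alone.

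Lists for the non-parenchymal cells of the liver did not differ from other genes. The stellate and mesothelial list had 14 of 20 genes marked (70%, adjusted p = 0.769), the cholangiocyte list 12 of 16 (75%, adjusted p = 0.578) and the endothelial list 12 of 20 (60%, adjusted p = 0.853), all by Fisher's exact test. Stellate and mesothelial members with a mark included Reln, Alcam and Pdgfra, and those without included Acta2, Col3a1 and Dcn. Hes1, Hnf1b and Slc4a2 were marked and Cldn4, Krt19 and Krt7 unmarked among bile duct genes. Of the endothelial genes Egfl7, Esam and Kdr, a receptor for vascular endothelial growth factor, were marked, and Cdh5, Clec4g and Emcn were not. The peak at Slc4a2 also covered the TSS of Cdk5, and that at Egfl7 the TSS of Gm20532. The stellate and endothelial shares were on either side of the share of other genes depending on the replicate, at 75% and 75% in replicate 1 and 60% and 50% in replicate 2.

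Genes of other organs were marked less often. The muscle list had 5 of 25 genes marked (20%, adjusted p = 9.88e-05), the list of other endoderm and kidney 4 of 24 (16.7%, adjusted p = 3.7e-05) and the germline list 5 of 25 (20%, adjusted p = 9.88e-05), by Fisher's exact test. Acta1, Actc1 and Actn2 of muscle, Cdx1, Cdx2 and Cpa1 of gut and pancreas, and Ddx4, Dmrt1 and Hormad1 of the germline were unmarked. The peak at several of the marked members covered the TSS of a neighbour, which was Zdhhc24 for Actn3, Klc3 for Ckm, Uqcrq for Gdf9, Rad51c for Tex14 and Spata48 for Zpbp. The peaks at Ryr2, Lgr5, Pax2 and Foxe1 covered no other protein-coding gene's TSS, and those at Pax2 and Foxe1 did not cover the gene's own TSS either. Of 1093 olfactory receptor genes 2 were marked (0.183%, 95% Wilson interval 0.0502 to 0.665%). These were Olfr56, whose peak also covered the TSS of Ifi47, and Olfr94, which was named after its value was seen, whereas Olfr1, Olfr10 and Olfr1000 were unmarked.

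Neuronal and glial genes were marked in 15 of 30 cases (50%, adjusted p = 0.256) and Hox genes in 20 of 39 (51.3%, adjusted p = 0.203), which did not pass Fisher's exact test. Gfap, Mbp and Pax6 were marked and Camk2a, Dcx and Gad1 unmarked. Hoxb2, Hoxb4 and Hoxa1 were marked and Hoxa10, Hoxa11 and Hoxa6 unmarked. The highest peaks at Gfap, Hoxb2 and Hoxb4 lay beside the gene's TSS without covering it. Both lists lay in CpG-rich sequence, and matched random lists would be marked at 81.4% and 90.2%, so that both passed that permutation test as lower (adjusted p = 6.25e-05 for each). The lists of dividing and general cell function were marked completely. Cell cycle genes were marked in 30 of 30 cases (adjusted p = 1.47e-05) and housekeeping genes in 25 of 25 (adjusted p = 7.02e-05, Fisher's exact test). Matched lists would be marked at 89.9% and 93.3%, and neither difference passed the permutation test (adjusted p = 0.117 and 0.432). With every member marked, neither list could have reached a higher share or passed that test as higher. No conclusion is drawn from it for these lists.

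**Figure D2:**
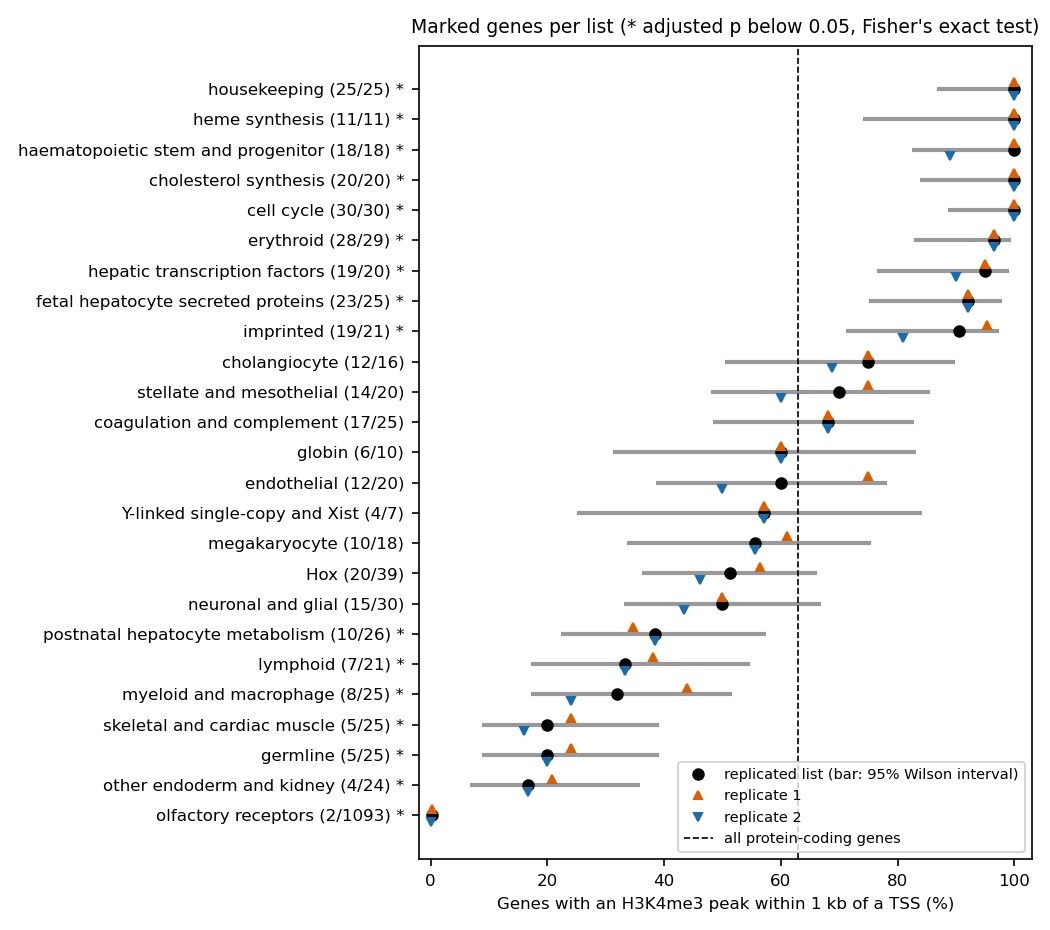
Percentage of each gene list with an H3K4me3 peak within 1 kb of a TSS (x axis), with the number of marked and tested members beside each name. Circles give the replicated list with its 95% Wilson interval, triangles the replicates, the dashed line all protein-coding genes (62.9%), and an asterisk an adjusted p below 0.05. The heme synthesis, stem and progenitor, cholesterol, cell cycle and housekeeping lists reached 100%, and olfactory receptors 0.183%.

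Imprinted genes, which are expressed from the allele of one parent, were marked in 19 of 21 cases (90.5%, adjusted p = 0.0180, Fisher's exact test). Gnas, Igf2 and Grb10 had the broadest domains, and the neighbouring genes Magel2 and Ndn were unmarked. By Fisher's exact test the call was lost in the list of replicate 2 alone (81.0%, adjusted p = 0.104), with the narrower promoter window (85.7%, adjusted p = 0.0582), with the 5′ end alone (76.2%, adjusted p = 0.184) and with stricter peaks (81.0%, adjusted p = 0.156). It was also lost in the CpG-matched permutation test (83.4% expected, adjusted p = 0.573). Among non-coding imprinted genes H19, Kcnq1ot1, Meg3 and Airn were marked and Rian was not. Of the Y-linked genes, Ddx3y, Eif2s3y, Uty and Kdm5d were marked, while Usp9y, Zfy1 and Zfy2 were not, so 4 of 7 were marked (57.1%, adjusted p = 0.777, Fisher's exact test). At Zfy1 97.2% of the 31-base words around the 5′ end occur more than once in the genome. Xist, the RNA that silences an X chromosome in female cells, had a domain of 3547.5 bp ± 1025 (SD, n = 2), and its antisense partner Tsix one of 760.5 bp ± 36.1 (SD, n = 2).

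Domain width was examined because broad H3K4me3 domains are known to mark genes of cell identity. Over 13457 genes with a domain in both replicates the median width was 2096.5 bp. Replicate 1 had the wider domain at 88.7% of genes, with a median of 2248 bp against 1932 bp, and widths correlated across genes with a Spearman's rho of 0.941. With peaks at most 1 kb apart merged, the broadest domain belonged to Ank1, at 20961.5 bp ± 8595 (SD, n = 2). Its widest single peak had 6965 bp in replicate 1 and 6636 bp in replicate 2, below the widest peaks of these lists at 12574 and 10240 bp. In replicate 1 it spanned 23033284 to 23060322 on chromosome 8, inside the gene at 22974844 to 23150497. The next was shared by Epb41, which encodes protein 4.1 of the red cell membrane skeleton, and Gm10300 at 17027 bp ± 4267 (SD, n = 2). Nfe2 followed at 16076 bp ± 8488 (SD, n = 2), and in replicate 1 its domain was fused with that of the neighbouring Cbx5 and Hnrnpa1, which had 15177 bp ± 9759 (SD, n = 2).

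The other genes among the 20 broadest fell into fewer domains because neighbours shared them. Ranbp10 and Tsnaxip1 had 13668.5 bp ± 4338, Gtpbp1 and Josd1 13389 bp ± 1464, Ubac1 12879.5 bp ± 1476, and Klf3, a Krüppel-like transcription factor, 12583 bp ± 448 (SD, n = 2). Dhrs11 and Mrm1 had 12031.5 bp ± 0.707 (SD, n = 2). A cluster of histone genes on chromosome 13 (Hist1h2ag, Hist1h2ah, Hist1h2bj, Hist1h2bk and Hist1h4i) shared 11887 bp ± 673 (SD, n = 2). H2afx shared 11574.5 bp ± 351 (SD, n = 2) with Hmbs, the heme synthesis enzyme hydroxymethylbilane synthase.

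Lists of the red cell program had the broadest domains. Medians were 8204 bp for heme synthesis (11 genes), 7536 bp for the erythroid list (28 genes) and 6696 bp for globins (6 genes), against 2096.5, 2092.5 and 2111 bp as the medians of random lists. Each exceeded all 10000 random lists of its size (permutation p = 0.0002, the smallest these random lists can give, adjusted p = 0.0007), although the 6 globin genes share 4 domains at 2 loci and are not independent draws. For globins the call also depended on merging, and without it their median was below that of random lists. Within the lists Fech had 10742 bp ± 2486, Cpox 9457 bp ± 793 and Dmtn 10737 bp ± 245 (SD, n = 2). Cell cycle genes had a median of 4548 bp (30 genes, permutation, adjusted p = 0.0007), led by E2f2 at 10052 bp ± 32.5, Pcna at 7993 bp ± 70.7 and Rrm2 at 7230.5 bp ± 326 (SD, n = 2). Hepatic transcription factors had 3608.5 bp (18 genes, permutation, adjusted p = 0.0007), with Gata6 at 8484.5 bp ± 4146, Prox1 at 6806.5 bp ± 1886 and Onecut2 at 5770.5 bp ± 1825 (SD, n = 2). Stem and progenitor genes had 3537 bp (16 genes, permutation, adjusted p = 0.00315), which without merging fell to 2465 bp and did not pass (adjusted p = 0.118, permutation), with Lyl1 at 7737.5 bp ± 1085, in a peak shared with Nfix, Runx1 at 7372.5 bp ± 343 and Meis1 at 7297 bp ± 884 (SD, n = 2). Housekeeping genes were moderately broad at 2978 bp (25 genes, permutation, adjusted p = 0.0139), with Snrpd3 at 5894 bp ± 199, Polr2a at 5542 bp ± 830 and Tbp at 5061 bp ± 901 (SD, n = 2), where the peaks at Snrpd3 and Tbp also covered the TSS of Gucd1 and of Psmb1.

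By the same permutation test, narrower domains than in random lists were found for Hox genes (median 782 bp, 18 genes, adjusted p = 0.0007), coagulation and complement (954 bp, 17 genes, adjusted p = 0.0012) and neuronal and glial genes (982 bp, 12 genes, adjusted p = 0.00373). Among the 3 broadest members of these lists, and so wider than their medians, were Hoxb2 at 2091 bp ± 468, Serpinc1 at 2201.5 bp ± 431 and Pax6 at 1583.5 bp ± 265 (SD, n = 2). The other 11 lists did not pass the test. Proteins secreted by fetal hepatocytes had 2364 bp (23 genes, permutation, adjusted p = 0.416), with Rbp4 at 3373 bp ± 133, Trf at 3069 bp ± 677 and Ttr at 2911 bp ± 817 (SD, n = 2). Cholesterol synthesis had 2591 bp (20 genes, adjusted p = 0.191), imprinted genes 2322 bp (17 genes, adjusted p = 0.518) and postnatal hepatocyte genes 1224 bp (9 genes, adjusted p = 0.0672, random-list permutation). Medians of the remaining lists, which are megakaryocyte, myeloid, lymphoid, endothelial, stellate and mesothelial, cholangiocyte and germline, lay between 1342.5 and 1605 bp. In replicate 2 alone the postnatal, megakaryocyte and stellate lists passed as narrower, with medians of 826, 935 and 1035 bp (permutation, adjusted p = 0.0042, 0.0126 and 0.0136). Without merging of peaks the globin median was 1287 bp and below that of random lists (permutation, adjusted p = 0.186), with merging over 3 kb it was 19222 bp, and against CpG-matched lists coagulation and complement no longer passed (adjusted p = 0.237) while secreted proteins passed as broader (adjusted p = 0.0238).

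**Figure D3:**
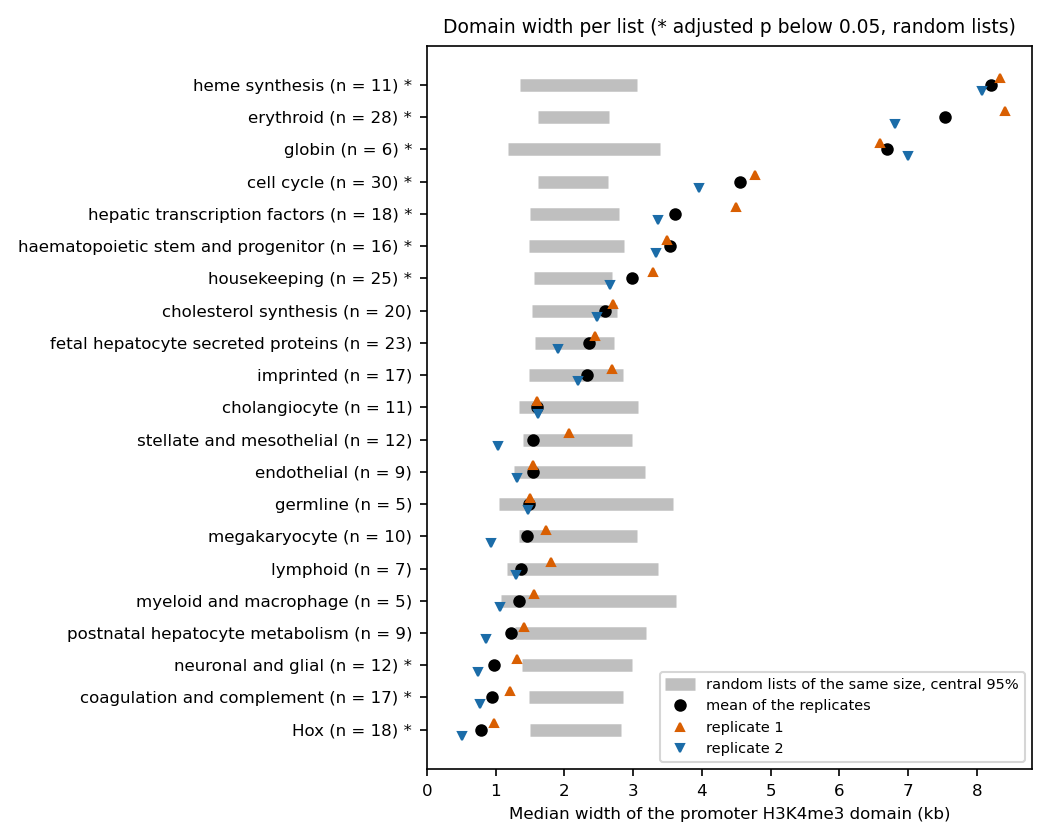
Median width of the promoter H3K4me3 domain per gene list (x axis, kb), with the number of genes marked in both replicates beside each name. Circles give the mean of the replicates, triangles each replicate, grey bars the central 95% of random lists of the same size, and an asterisk an adjusted p below 0.05. The heme synthesis, erythroid and globin lists lie far to the right of their bars, and the Hox list to the left.

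The broadest 5% of domains held 673 genes with at least 5128 bp, in 517 distinct domains. They included 22 of 28 erythroid genes (78.6%, adjusted p = 1.22e-22), 9 of 11 heme synthesis genes (81.8%, adjusted p = 1.17e-09), 5 of 6 globin genes (83.3%, adjusted p = 1.11e-05) and 10 of 30 cell cycle genes (33.3%, adjusted p = 9.22e-06), by Fisher's exact test. The 5 globin genes lie in 3 domains, which the test counts as 5. Hepatic transcription factors (5 of 18, adjusted p = 0.00766) and stem and progenitor genes (4 of 16, adjusted p = 0.0290) also passed Fisher's exact test. Without merging, 0% of globin genes, 11.1% of hepatic transcription factors and 18.8% of stem and progenitor genes were in the broadest 5%, and 3 lists were called in place of 6. Imprinted genes had 2 of 17 members there and were called in replicate 2 alone (23.5%, adjusted p = 0.0313, Fisher's exact test).

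Within the globin loci the genes of the adult red cell were marked and those of the embryonic red cell were not. The adult genes Hbb-bt (6876.5 bp ± 384), Hbb-bs (4435 bp ± 60.8), Hba-a1 (6515 bp ± 683) and Hba-a2 (8648.5 bp ± 2129) were marked in both replicates (SD, n = 2). The theta genes were marked as well, Hbq1b in the same domain as Hba-a1 and Hbq1a in that of Hba-a2. The highest peaks at Hbb-bt, Hba-a1, Hba-a2 and Hbq1a lay beside a TSS of the gene without covering it. In the replicated list no peak covered the 5′ end of Hba-a1 at 32283511 or of Hba-a2 at 32296489. In replicate 1 the domain of Hba-a1 began at 32284356, downstream of that 5′ end. Of the 31-base words around the 5′ end, 74.99% at Hba-a1, 81.0% at Hba-a2, 36.3% at Hbb-bs and 43.6% at Hbb-bt occur more than once in the genome, which limits how far marks and widths can be assigned to a single copy. The embryonic genes Hbb-y, Hbb-bh1 and Hba-x were unmarked in both replicates, as was Hbb-bh2. With 6 of 10 members marked, the list did not pass the test against other genes (60%, adjusted p = 1, Fisher's exact test), but CpG-matched lists would be marked at 22.1% and the list passed that permutation test as higher (adjusted p = 0.00183). At the adult genes the mark was broken into several peaks around the gene bodies. Between Hbb-y and Olfr66, where the locus control region of the beta-globin genes lies, the replicated list had 4 weak peaks from 103858780 to 103870765 on chromosome 7, with signal values of 3.25 to 4.25, chosen after their values were seen. By comparison the highest peak at Hba-a2, which began at 32297166 near the 3′ end of the gene, had a signal value of 18.2. The peak at the promoter of Nprl3 had one of 41.4.

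**Figure D4:**
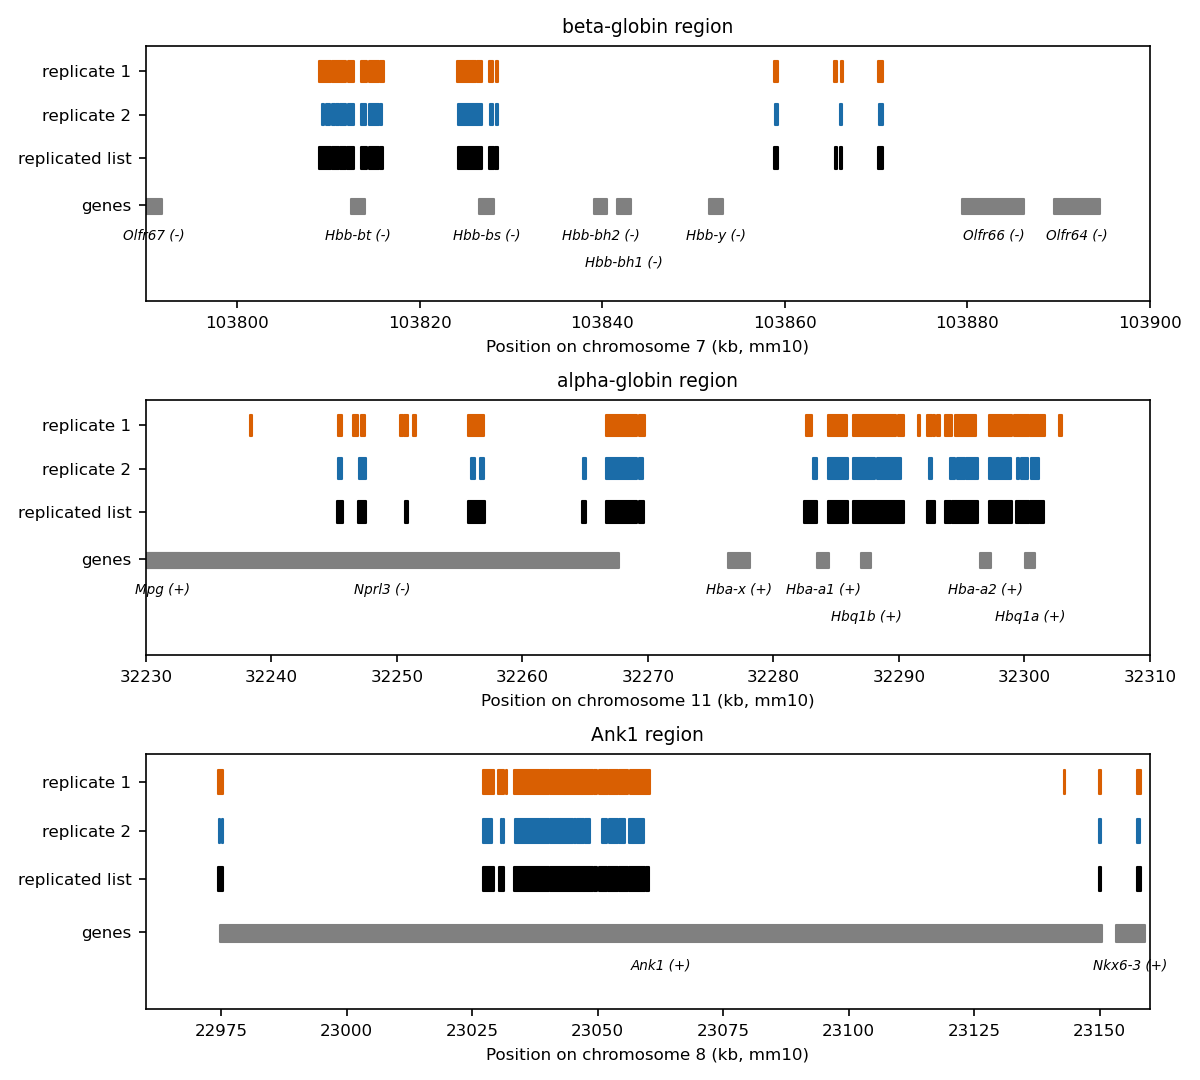
Peaks of replicate 1, replicate 2 and the replicated list (rows of boxes) and protein-coding genes with their strand (grey boxes) along the beta-globin, alpha-globin and Ank1 regions, with position in kb of mm10 on each x axis. Peaks surround Hbb-bt, Hbb-bs, Hba-a1, Hbq1b, Hba-a2 and Hbq1a and are missing at Hbb-bh1, Hbb-bh2, Hbb-y and Hba-x, and the Ank1 domain lies within the gene.

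The highest signal value of the replicated list was 84.0 at Arf1, a small GTPase of Golgi transport, on chromosome 11 at 59225914 to 59229207. It was followed by Odc1, which starts polyamine synthesis, at 83.6, Ssb, the RNA-binding protein La, at 83.4, Ube2s, a ubiquitin-conjugating enzyme of mitotic exit, at 81.9 and Luc7l3, a splicing factor, at 80.3. Slc11a2, the iron transporter DMT1, shared its peak with Gm5475 at 79.8, and Mical3 had the same value. Ssbp3 had 79.7, and Wtap, part of the RNA methylation complex, had 79.2. Their domains were wider than the median of 2096.5 bp, from 2668 bp ± 43.8 at Ssb to 6179.5 bp ± 613 at Slc11a2 (SD, n = 2), and those of Slc11a2, Gm5475, Ssbp3 and Luc7l3 were among the broadest 5%.

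Away from promoters, 3464 peaks (15.5% of the replicated list) lay more than 5 kb from any TSS. Their median signal value of 4.61 was below the 15.1 of the other peaks, and their median width was 532 bp. The highest was on chromosome 12 at 8640337 to 8641779, intergenic, 32355 bp from the nearest TSS, that of Pum2, with a signal value of 57.0. The next was intergenic on chromosome 16 at 64872828 to 64874421, 20126 bp from Cggbp1, with 55.9. On chromosome 5 a peak at 23417619 to 23419531 in an intron of the non-coding gene 5031425E22Rik, 14910 bp from Kmt2e, had 46.3. Intergenic sequence on chromosome 7 at 73616862 to 73619730, 7705 bp from the non-coding Gm44738, had 45.4, and an intronic peak in Chid1 at 141505503 to 141507004 on the same chromosome had 43.8.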

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

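No test bears on the peaks described here, which are given because they lie in data that the comparisons did not use. The comparisons were limited to the assembled chromosomes, and the replicated list had a further 9 peaks on 5 scaffolds outside them. Replicate 1 and replicate 2 had 9 such peaks each and the pooled list 10. Of the 9, 6 lay within 1 kb of the TSS of an annotated gene. The highest, with a signal value of 34.7 and a width of 2160 bp, lay at a predicted gene on an unlocalized scaffold of chromosome 4. The peak at Vamp7, a protein of vesicle fusion, had a signal value of 24.8, and that at Tmlhe, an enzyme of carnitine synthesis, 7.59, both on an unlocalized scaffold of the X chromosome. No biological explanation was tested.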

How the results depend on the processing

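All alternatives given here were planned. The count of marked protein-coding genes and the CpG difference kept their direction under each alternative run, with 12988 to 14092 genes and differences of 0.365 to 0.543. The erythroid, heme synthesis and cell cycle lists kept their calls of broader domains and of membership in the broadest 5% under each alternative run. Of the results for the share of lists marked, 182 of 208 were unchanged, of those for breadth 115 of 131, and of those for the broadest domains 145 of 155. For a list, unchanged means the same direction and side of the threshold. Each total also holds the number of lists called under each alternative, which was judged only by its closeness to that of the main settings. Unless a reason is given, the cause of a change was not tested. Sequencing depth is unknown, so the weak peaks that separate the replicates cannot be referred to a depth.

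Requiring an overlap of at least 50% of either peak gave 67.4% shared for replicate 1 and 95.5% for replicate 2, at least 50% of both peaks 59.6% and 76.8%, and −log10 q of at least 2 gave 68.7% and 98.8%. Among the 11071 highest peaks of each list 94.2% and 96.1% were shared. Pearson's r with the stricter q was 0.903. The share at promoters within 2 kb was 75.04%, from the wider window. The asymmetry without merging was 628.5 bp.

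For the share marked, a window of 500 bp left imprinted genes at 85.7% and not called. Within 2 kb endothelial genes, at 65%, changed to above other genes, uncalled. With the 5′ end alone coagulation and complement genes were at 56% and below other genes, globins at 60% and above, both uncalled, and the calls of stem and progenitor genes (77.8%) and imprinted genes (76.2%) were lost. Stricter q put imprinted genes at 81.0% and uncalled. By summit the calls of hepatic transcription factors (80%) and heme synthesis (90.9%) were lost. Against random lists matched on CpG content the shares are the same by construction and the comparison changed. Coagulation and complement (68%) and globins (60%) became called as higher, the latter having been below other genes, and neuronal and glial (50%) and Hox genes (51.3%) became called as lower. Postnatal hepatocyte (38.5%), megakaryocyte (55.6%), myeloid (32%) and endothelial genes (60%) changed to above expectation, uncalled. Cholesterol synthesis (100%), cell cycle (100%), housekeeping (100%), imprinted (90.5%) and lymphoid genes (33.3%) lost their calls. Of these, the lists at 100% could not have passed as higher, so no conclusion is drawn from their lost calls. For each replicate alone the share was 60 to 75% for stellate and mesothelial, 50 to 75% for endothelial, 81.0 to 95.2% for imprinted and 24 to 44% for myeloid genes. The first 2 lists changed direction without a call, imprinted genes lost their call without replicate 1 and myeloid genes without replicate 2.

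For breadth without merging, medians were 1446.5 bp for secreted proteins, 1762 bp for imprinted genes and 1287 bp for globins, all 3 turned to narrower and uncalled. Stem and progenitor genes, at 2465 bp, lost their call. Postnatal hepatocyte (894 bp), megakaryocyte (1095.5 bp), myeloid (774 bp) and stellate genes (598 bp) became called as narrower. With stricter q secreted proteins turned to narrower at 1862 bp, uncalled, and coagulation and complement lost its call at 1366 bp. Matched on CpG content, secreted proteins (2364 bp) became called as broader and coagulation and complement (953.5 bp) lost its call. For each replicate alone the medians were 1908 to 2447 bp for secreted proteins, which turned without replicate 1. They were 826 to 1408 bp for postnatal, 935 to 1734.5 bp for megakaryocyte and 1035 to 1652 bp for stellate genes, each called as narrower without replicate 1.

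Of the broadest 5%, no merging put 0% of globins there, which turned to below other genes, and 11.1% of hepatic transcription factors and 18.8% of stem and progenitor genes, which lost their calls, so that 3 lists were called. Merging over 3 kb put 11.1% of hepatic transcription factors there, which lost their call, and 9.09% of cholangiocyte genes, which turned to above. Stricter q put 0% of stellate genes there, turned to below. For each replicate alone the share was 0 to 9.09% for cholangiocyte, 0 to 10% for megakaryocyte and 15.8 to 23.5% for imprinted genes, the last called without replicate 1.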

Other observations

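The gene families, the long non-coding genes, the distance from Slc25a37 to the nearest peak, the restriction to domains with the TSS of a single gene and the comparison of Y-linked genes were chosen after the data had been seen, as were the lists of other organs as a comparison for replicate 1. The broad erythroid and heme synthesis domains and the unmarked Slc25a37 had been seen before the tests of them were written, the repeated words of list genes before the test over all CpG-rich promoters was written, and the measure for the Y-linked genes was changed from signal values to widths after the former had been seen. Among gene families taken from the annotation's symbols, histone, ribosomal, proteasome and zinc finger genes were marked more often than other genes. Neither these families nor those with low shares were compared with lists matched on CpG content, so their shares are not separated from it. Replication-dependent histones were marked in 59 of 67 cases (88.1%, adjusted p = 6.27e-06, Fisher's exact test) with a median domain of 6312 bp, at percentile 100 of 10000 random lists (permutation, adjusted p = 0.000467), but these genes are clustered and share merged domains while the random lists draw scattered genes, so fusion of neighbours is not excluded. Cytosolic ribosomal proteins were marked in 76 of 79 cases (96.2%, adjusted p = 6.72e-12) with a median of 3153 bp, mitochondrial ribosomal proteins in 78 of 78 (adjusted p = 5.2e-16) with 2120 bp, and proteasome subunits in 38 of 39 (97.4%, adjusted p = 5.35e-07), by Fisher's exact test. Zinc finger genes named Zfp were marked in 335 of 394 cases (85.0%, adjusted p = 6.44e-22, Fisher's exact test), but their median domain of 1683 bp was narrower than in each of the random lists (permutation, adjusted p = 0.000467). Tubulins were marked in 19 of 23 cases and did not pass (adjusted p = 0.0535, Fisher's exact test).

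Clustered protocadherins, which give neurons their surface identity, were marked in 6 of 57 cases (10.5%, adjusted p = 5.2e-16, Fisher's exact test), vomeronasal receptors in 1 of 331 (0.302%, adjusted p = 2.34e-141), keratin-associated proteins in 0 of 57 (adjusted p = 1.57e-24) and beta-defensins in 0 of 42 (adjusted p = 2.42e-18). The 95% Wilson intervals allow shares of up to 6.31% for the keratin-associated proteins and 8.38% for the beta-defensins. Low shares were also found for 10 of 57 cytochrome P450 genes of family 2 (17.5%, adjusted p = 4.64e-12), 1 of 21 UDP glucuronosyltransferases (4.76%, adjusted p = 4.65e-08) and 3 of 24 serpins of clade A (12.5%, adjusted p = 5.68e-07), by Fisher's exact test. Of 10120 long non-coding genes 2261 (22.3%) were marked, 645 of them away from any protein-coding promoter. The highest of these was 6720427I07Rik, with a signal value of 58.4. Snhg5, a host of small nucleolar RNAs, and Mir142hg, the host of a microRNA of blood cells, were the lowest of the 10 highest with 51.4 and 51.0 and were picked for what is known of them. By chromosome the marked share of protein-coding genes went from 76.7% on chromosome 12 to 51.1% on chromosome 14, 44.9% on X and 2.19% on Y.

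The broad domains of the erythroid and heme synthesis genes were the first pattern weighed. Promoter CpG content was argued against, since both lists stayed at percentile 100 among random lists matched on CpG deciles. Fusion of neighbouring promoters was argued against too, since both lists stayed at percentile 100 among genes whose domain held no other gene's TSS, over 24 erythroid and 6 heme synthesis genes. Signal value was not weighed as a source of the width. In the replicated list it was 50.3 at Dmtn, 66.6 at Fech and 52.4 at Cpox, against 8.15 at Rbp4, 6.78 at Trf and 8.99 at Ttr. A high value also occurred with a narrower domain, 83.4 with 2668 bp at Ssb. The peaks come from whole liver, so these widths are not separated from the share of cells that carry the mark. The design has a single group, so no biological explanation was tested.

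A hypothesis that peaks more than 5 kb from any TSS accompany these genes was tested. Of the erythroid and heme synthesis genes, 16 of 38 (42.1%) had one within 50 kb of the 5′ end, against 19.05% of other marked genes (odds ratio 3.09, 95% interval 1.52 to 6.17, p = 0.00123, Fisher's exact test). For secreted hepatocyte proteins the odds ratio was 0.635 (3 of 23, p = 0.601, Fisher's exact test). By this rule an outlying peak of a gene's own broad domain can count, so the result is not separate from the breadth of these lists. Taken singly, the erythroid list passed (13 of 28, adjusted p = 0.0101), as did the globin list (6 of 6, adjusted p = 0.00107), whose genes lie at only 2 loci and are counted as 6, and heme synthesis did not (3 of 11, adjusted p = 0.945, Fisher's exact test). Shares of 42.9% for lymphoid, 36.8% for hepatic transcription factor and 36% for housekeeping genes did not pass Fisher's exact test either (adjusted p = 0.388, 0.383 and 0.299).

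Marks at CpG-poor promoters were examined with the same lists. In the lowest 3 deciles of CpG content, 32 of 37 erythroid, globin, heme synthesis and secreted hepatocyte genes (86.5%) were marked, against 9.80% of other genes (odds ratio 58.9, 95% interval 22.7 to 194, p = 2.76e-27, Fisher's exact test). The marks of these lists were already counted in the tests above, so this is not separate support. The other genes also include CpG-poor olfactory receptors such as Olfr1, Olfr10 and Olfr1000, which were unmarked. Broad examples were Nfe2, Slc4a1, which encodes the red cell anion exchanger, at 10546.5 bp ± 457, and Hemgn at 9979.5 bp ± 302 (SD, n = 2). CpG-poor promoters with broad domains outside these lists included Tnfrsf14 at 8322.5 bp ± 98.3, Tmcc2 at 7473.5 bp ± 738, and Ackr1, the Duffy antigen of red cells, at 6889.5 bp ± 46.0 (SD, n = 2), all named after their values were seen.

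The missing peak at Slc25a37 was the second pattern weighed. The nearest peak of the replicated list lay 50815 bp from the gene, but this leaves open whether a mark lies elsewhere in the gene, since 71.5% of the words of the gene body are repeated too. Reads shared with a near-identical copy remain a candidate explanation, since 100% of the promoter's 31-base words occur more than once on the chromosomes, against a median of 1.22% and a highest value of 16.7% over the 28 marked erythroid genes. Repeated words did not preclude a peak within 1 kb of a TSS, since Hba-a1 (74.99%), Hba-a2 (81.0%) and Kng1 (70.3%) were marked. The highest peaks at Hba-a1 and Hba-a2 did not cover the TSS, however. Among list genes other than olfactory receptors, 3 marked and 2 unmarked ones, Slc25a37 and Zfy1, had at least 50%. Over all promoters in the upper 5 CpG deciles, 119 of 170 with at least 50% repeated words (70%) had no peak, against 5.95% of the others (odds ratio 36.8, 95% interval 26.0 to 52.7, p = 6.31e-100, Fisher's exact test). Genes with repeated promoters may also truly lack the mark in this tissue. This comparison cannot tell that from reads lost to shared sequence.

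The peaks of replicate 1 without a counterpart in replicate 2 were the third pattern weighed. Weak signal remains open as their source, since 99.5% of the 8710 lay below the median signal value of the list and 94.2% of the 11071 highest peaks were shared, but nearness to the calling threshold is not shown, since 74.1% of the 8710 had a −log10 q of at least 2 and that filter left 68.7% of the list shared. A different mix of cell types also remains open, since among genes unmarked in replicate 2, 16 of 64 members of the megakaryocyte, myeloid, lymphoid, endothelial, stellate and cholangiocyte lists were marked in replicate 1, among them Adgre1, Lyz2, Cdh5, Lyve1, Stab2 and Dcn (odds ratio 4.23, 95% interval 2.23 to 7.64, p = 1.2e-05, Fisher's exact test), against 4.4 expected in CpG-matched draws (p = 0.0002, the smallest the draws can give). The gain lay mostly in the endothelial (5 of 10), myeloid (5 of 19) and stellate (3 of 8) lists, while the lymphoid (1 of 14), megakaryocyte (1 of 8) and cholangiocyte (1 of 5) lists had 1 gene each. In lists of other organs (neuronal, muscle, endoderm and kidney, Hox and germline) 11 of 99 genes gained a mark. This was fewer than the 18.9 of CpG-matched draws (permutation p = 0.0354). The cell type lists gained marks more often than these (odds ratio 2.65, 95% interval 1.06 to 6.87, p = 0.0298, Fisher's exact test). However, Des stood in both the stellate and the muscle list and was counted on both sides of that comparison. Its groups are therefore not separate, and no conclusion is drawn from its p. A more sensitive list would show weak marks of rare cell types as well, so both explanations may apply.

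All 4 marked Y-linked genes had wider domains in replicate 2, against 11.1% of autosomal genes (p = 0.000151, exact binomial test). The test counts the 4 genes as independent, but they lie on the same chromosome and were measured in the same 2 libraries. Its p therefore does not measure how far the pools differ. Their median log2 ratio of widths, replicate 2 over replicate 1, was 0.74 against −0.19 for autosomal and −0.17 for X-linked genes, at percentile 100 of autosomal sets of similar width. A larger share of male embryos in the pool behind replicate 2 may account for this, as a hypothesis found on the same data, since the labels give no numbers of male and female embryos.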
